A study of Mus musculus with 4 samples.

How the data were processed

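Total RNA from vector-infected and Cre-infected fibroblasts, 2 samples each, was labelled with biotin and hybridised to 4 Affymetrix arrays, per the labels. The deposited intensity values were 1 table of linear probe set signals, made with MAS5 per the submitters' processing notes. The MAS5 version, its background settings and its scaling target are not given in the sources used here. The deposited values had the same mean, 500, on every array once the lowest and highest 2% of probe sets were left out, which is what a global scaling of each array gives. Such a scaling removes any change shared by most genes, so each difference is relative to the average of its array. Detection calls were not used here. The table had 0 missing values, and signals ran from 0.0594 to 31695.

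Of the probe sets, 64 controls were left out, which left 45037. The platform annotation gave 1 gene symbol for 34945 of them, several for 932 and none for 9160, and no gene was named from a probe set with several. Gene identifiers of 34741 of the 34945 were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No genome build is named for the arrays, so that assembly served for names and for which genes neighbour each other. One gene of the rule for named genes is not reported here.

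Signals were analysed as log2(signal + 9.96), where 9.96 is the 20th percentile of all values, so fold changes understate the change of dim genes. The upper 50% of probe sets by mean log2 signal were tested, 22519 in all, with the boundary at a signal near 62.8. A gene with several tested probe sets was read through its brightest, which left 10714 genes, and the text gives other probe sets of the genes whose tested probe sets differed in sign. Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 2-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Group was the only term, with 2 residual degrees of freedom. An exact test of 2 arrays against 2 cannot give a p below 0.333. Every adjusted p in the text comes from limma or its set tests.

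Before the data were examined, 33 gene lists, the groups, the tests and the rule for named genes were fixed. Lists with at least 5 tested genes, 27 in all, were tested with limma's camera at a preset correlation of 0.01 on the brightest probe sets, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry were run beside it. Intervals of list medians come from 10000 bootstrap resamples of the genes and cover the spread between genes only. The rule named the targeted gene, its tested complex partners, up to 12 genes with the largest rise and up to 12 with the largest fall among those past the threshold and without overlap between groups, and leading members of each list. As no gene passed, the 12 were taken from genes with an unadjusted p under 0.01 and no overlap, as the rule provided, and 2 members were named per list. This gave 80 genes.

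The gene test was checked on simulated data for the knockout against wild-type comparison, with 200 of 22519 probe sets changed. With the difference between replicate numbers simulated as measured and moderated spreads, limma without a replicate term recovered 0% of 2-fold and 0% of 4-fold changes, with 0 false calls. With the replicate number as a term it recovered 90% and 100%, with 17 false calls, and with no simulated difference between numbers the fit without the term recovered 84% and 100%, with 25 false calls. An earlier simulation with unmoderated spreads, which rest on 1 residual degree of freedom per probe set, was kept. There the fit with the number as a term recovered 0% of both sizes, and without a simulated number difference the fit without the term recovered 23% and 48%. For lists, 10 of 30 lists of 20 random genes among 10714 were shifted by -0.5. Camera with the preset correlation recovered 10 of 10 in both simulations. With an estimated correlation it recovered 0 with moderated and 9 with unmoderated spreads. At most 1 of 20 unshifted lists was called. The simulated noise was independent between genes, so this gives no false-call rate for lists whose genes move together.

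Alternatives were quantile, median and cyclic loess normalization, pseudocounts of 1 and of the median signal (64.9), no filter and a filter keeping 30%, eBayes without a trend and with robust estimation, the mean of a gene's probe sets, an adjusted p threshold of 0.01, the replicate number as a block, and leaving out each array. Counts of genes at least 2-fold different at both replicate numbers, and the list of neighbours without Kif22, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.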

Results

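Messenger RNA levels were measured on 4 Affymetrix arrays of immortalised mouse embryonic fibroblasts (MEFs) that carried a conditional, loxP-flanked PA1 allele. A retrovirus carrying Cre recombinase, which deletes DNA between loxP sites, gave the PA1 knockout cells (2 arrays), and the empty retroviral vector gave the PA1 wild-type cells (2 arrays). Both cultures were selected with puromycin. PA1 was read here as Pagr1a, which encodes the PTIP-associated protein of the KMT2C and KMT2D histone methyltransferase complexes. The study asked which genes depend on PA1. Each array gave MAS5 signals for 45037 probe sets other than controls, with medians between 63.2 and 66.4, and the number of arrays limits the precision. The labels number the arrays of each group 1 and 2 without saying whether these were separate cultures, so p-values measure only the spread between these samples, which may in part be technical.

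Pagr1a itself was 11.4-fold lower in the knockout arrays on the log2(signal + 9.96) scale. Its brightest probe set read 1365 ± 34.4 in wild-type cells and 110.5 ± 4.15 in knockout cells (mean ± SD, n = 2 each), a log2 difference of -3.51 with a standard error of 0.249. A second probe set read 516 ± 0.81 against 38.3 ± 0.245, and a dim one 171 ± 8.69 against 8.55 ± 0.931. The difference was -3.52 between the arrays numbered 1 and -3.50 between those numbered 2. With genotype as the only term, Pagr1a missed the threshold over all 22519 probe sets tested (limma adjusted p = 0.876). It passed when adjusted over the list alone, which holds this 1 gene. Which part of the gene the allele removes is not given in the sources used here. If these probe sets lay outside it, they would not check the deletion itself.

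The partners of PA1 in the KMT2C and KMT2D complexes differed little. Of the 9 partners tested, 6 were higher and 3 lower in the knockout arrays, and 0 passed, whether adjusted over all genes or adjusted over the list alone. Paxip1, which encodes PTIP, read 719 ± 108 in wild-type and 990 ± 261 in knockout cells (log2 difference 0.44, SE 0.307). Ncoa6 differed by 0.36, the demethylase gene Kdm6a by 0.41, and the core subunit genes Wdr5 and Rbbp5 by 0.30 and 0.28. Kmt2d differed by 0.23, Kmt2c by -0.05, Ash2l by -0.05 and Dpy30 by -0.22. A second probe set of Ash2l gave 0.88 and one of Kdm6a gave -0.06, while those of Kmt2c ranged from -0.28 to 0.01. As a group the partners had a median of 0.28 (95% bootstrap interval -0.05 to 0.42), which camera did not call (adjusted p = 0.105).

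**Figure D1:**
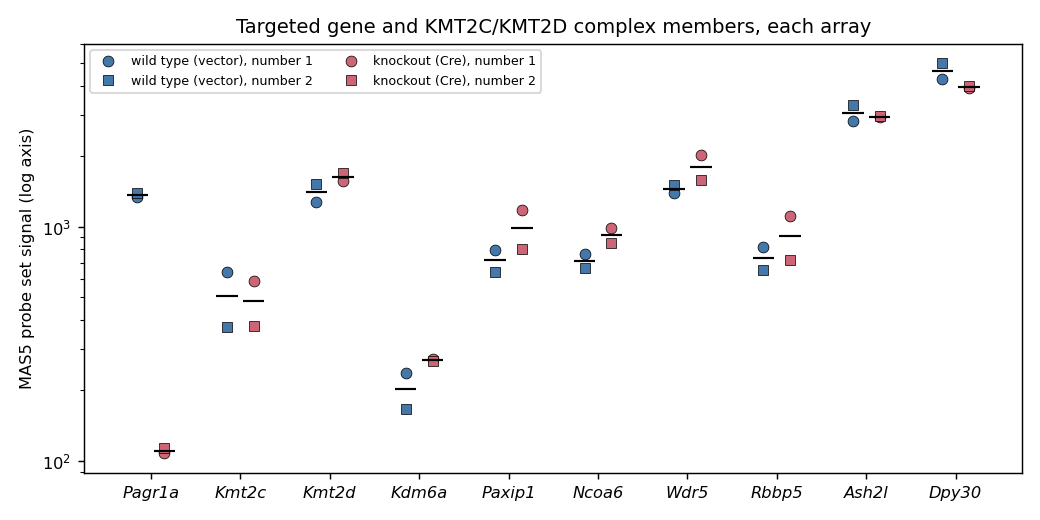
Signal of the brightest probe set of Pagr1a and of 9 partner genes on each of the 4 arrays (log axis, MAS5 signal); colours separate wild type from knockout, circles and squares are replicate numbers 1 and 2, and lines are group means. Pagr1a reads 1340 and 1389 in wild type against 108 and 113 in the knockout, while each partner gene's group means lie within 1.38-fold of each other.

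Beyond Pagr1a, the genes with the largest differences were mostly lower in the knockout arrays. They included Il1rn (the interleukin-1 receptor antagonist), which read 558 ± 243 in wild-type and 58.2 ± 8.43 in knockout cells, and Cdc42ep2 (an effector of the GTPase Cdc42), which read 1565 ± 351 and 215 ± 65.8. Gap43, a growth cone protein gene, read 921 ± 422 and 123 ± 60.5, and Plac8 read 1246 ± 299 and 239 ± 2.2. The transcription factor gene Cebpd read 4326 ± 1055 and 872 ± 575. On the log2 scale, Il1rn differed by -3.00, Aldh1a7 by -2.99, Cdc42ep2 by -2.82, Gap43 by -2.81 and Cebpd by -2.45. The glutamate transporter gene Slc1a3 differed by -2.34, Plac8 by -2.31, the hyaluronan-binding protein gene Cemip by -2.30, the receptor kinase gene Ntrk3 by -2.02, Kif22 by -1.97 and Bcl3 by -1.93. The other tested probe sets of Kif22 differed by only -0.13 and -0.03. On the higher side stood Lce1h (82.2 ± 11.9 against 438 ± 124, log2 difference 2.26), the chaperone gene Hspa4l (1.18), the laminin chain gene Lamb1 (0.95) and Cttnbp2nl (0.92). These 15 genes were ranked among those with an unadjusted limma p under 0.01 and no overlap between groups. There were 33 such genes on the lower side, Pagr1a among them, and 4 on the higher side.

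With genotype as the only term, a fit that counts any difference between replicate numbers as spread, no gene passed limma at an adjusted p under 0.05: the counts were 0 of 22519 probe sets and 0 of 10714 genes, with 0 also under a robust variance model and without an intensity trend. At an unadjusted p under 0.05 there were 440 probe sets (167 higher, 273 lower) and 231 genes (87 higher, 144 lower), against 536 genes that chance would give. Knockout and wild-type values did not overlap for 26.3% of genes, against 33.3% by chance. Both chance values assume 4 exchangeable arrays, which the correlations between arrays do not bear out, so neither shows fewer differences than chance. In simulated data with the measured difference between numbers, this fit recovered 0% of 4-fold changes, so a count of 0 does not show that genes were unchanged. As given below under the dependence on processing, genes did pass with the replicate number as a block, Pagr1a among them.

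The arrays stood apart by replicate number as well as by genotype. Across all tested probe sets, log2 signals correlated at 0.971 and 0.977 between the wild-type and knockout arrays of the same number, and at 0.918 and 0.920 between the arrays of the same genotype. Genotype differences were therefore also read within each number. Between the arrays numbered 1, 265 genes were at least 2-fold lower and 146 at least 2-fold higher in the knockout. Between those numbered 2, 228 were lower and 96 higher. At both numbers, 89 genes were at least 2-fold lower, 20 at least 2-fold higher, and 6 went opposite ways. Across genes, which are not independent replicates, the differences at the 2 numbers correlated at 0.437. Without the filter on dim probe sets the counts were 172 lower and 94 higher, and with a pseudocount at the median signal they were 56 and 5. The count at both numbers was chosen after the arrays had been compared.

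**Figure D2:**
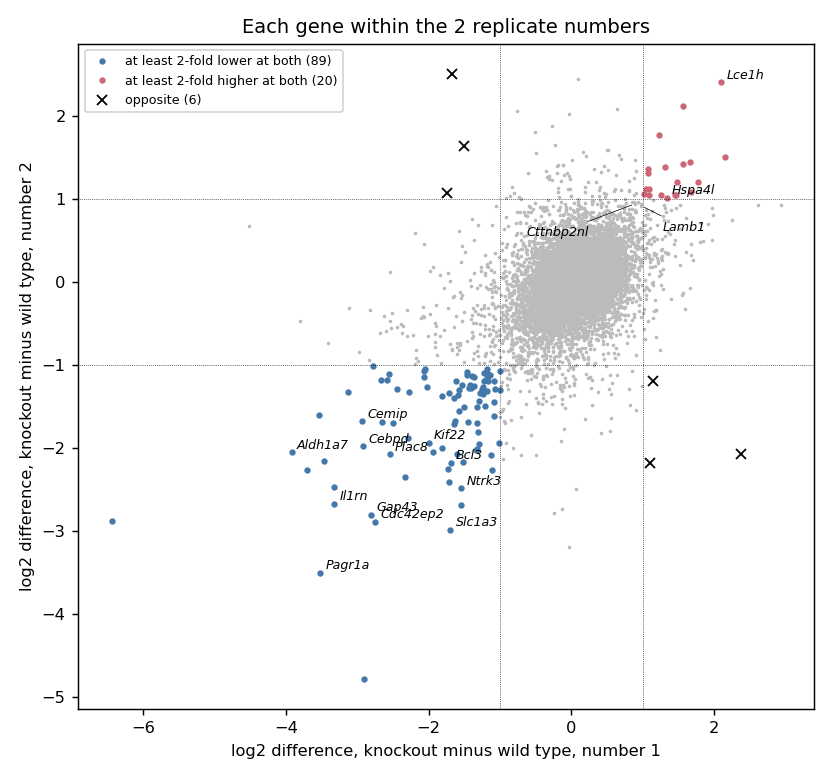
Log2 difference, knockout minus wild type, for each of 10714 genes between the arrays numbered 1 (horizontal axis) and between those numbered 2 (vertical axis); dotted lines mark 2-fold and labels give the named genes. The lower left corner holds 89 genes and the upper right corner 20, and crosses are the 6 genes with opposite differences.

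**Figure D3:**
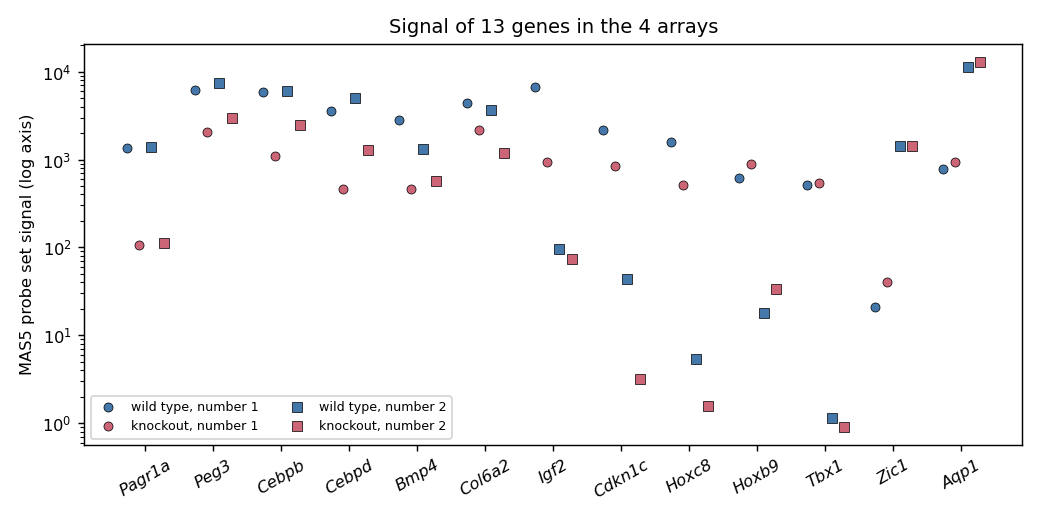
Signal of 13 genes on each of the 4 arrays (log axis, MAS5 signal); colours separate wild type from knockout, and circles and squares are replicate numbers 1 and 2. Pagr1a, Peg3, Cebpb and Cebpd are lower in both knockout arrays, while Hoxc8, Tbx1, Zic1 and Aqp1 separate the 2 numbers, with Aqp1 at 781 and 927 for number 1 and 11290 and 12820 for number 2.

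Among 27 gene lists with at least 5 tested genes, camera called 14, all of them lower in the knockout relative to other genes (preset correlation, limma). With an estimated correlation 0 lists were called (smallest adjusted p = 0.351, 1 list at an unadjusted p under 0.05), and with fry 0 were called (smallest adjusted p = 0.183, 3 lists at an unadjusted p under 0.05). In simulated data, camera with an estimated correlation recovered 0 of 10 shifted lists with moderated spreads and 9 with unmoderated ones. The simulated noise was independent between genes, whereas genes of a real list may move together, so neither recovery carries over directly. The count of 0 with an estimated correlation thus does not show that the lists were unchanged. Nor do the simulations give a reason to set that count aside. With genotype as the only term, no member of any list passed when adjusted over all genes. Statements below on members that passed over their list alone come from the same fit. With the replicate number as a block some members did pass, as given below under the dependence on processing. Fits without 1 array, given below for many lists, hold unequal replicate numbers in the 2 genotypes. Their medians and calls therefore also carry part of the difference between numbers. Number 2 minus number 1 had a median of -0.80 for collagens, -0.98 for interferon-stimulated genes and 0.59 for p53 targets. Such shifts do not test genotype alone. The first 4 calls described here were made whichever array was left out. They are not independent of each other. Members that also stand in another list were 2 of 12 for adipogenesis and 3 of 15 for glucocorticoid receptor targets. For imprinted genes they were 3 of 14, and for fibroblast markers 4 of 13. Cebpd counts in both the adipogenesis and the glucocorticoid list, and Dcn in both the imprinted and the fibroblast list.

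Adipogenesis genes fell as a group (camera adjusted p = 2.68e-05; adjusted p = 0.351 with an estimated correlation), with a median log2 difference of -0.47 over 12 tested genes, of which 11 were below 0 and 9 were lower at both numbers. The 2 that passed when adjusted over the list alone were Cebpd and Cebpb, transcription factors that act early in adipocyte differentiation. Cebpb read 5982 ± 50.8 in wild-type and 1775 ± 973 in knockout cells (-1.86; SE 0.422). Dlk1, which inhibits adipocyte differentiation, differed by -1.13 and Klf4 by -1.54. A second probe set of Cebpd differed by -0.57. Without the filter on dim probe sets the median was -0.28 (adjusted p = 0.0173), and with the stricter filter -0.87.

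Glucocorticoid receptor targets also fell as a group (camera adjusted p = 0.00161; adjusted p = 0.351 with an estimated correlation), with a median of -0.44 over 15 genes, 11 of them below 0. Cebpd, Ddit4 (2603 ± 37.7 against 1121 ± 315) and Errfi1 (-1.24) were at least 2-fold lower, as was Cdkn1c (-1.68, SE 2.63). Per1, Fkbp5, Glul and Tsc22d3, which the receptor is known to induce, were above 0, at 0.36, 0.31, 0.23 and 0.12. The median was -0.20 without the filter on dim probe sets (adjusted p = 0.0452) and -0.22 without the knockout array numbered 2 (0.00454). None passed when adjusted over the list alone.

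Imprinted genes fell as a group (camera adjusted p = 0.000688; adjusted p = 0.351 with an estimated correlation), with a median of -0.67 over 14 genes, 12 of them below 0 and 11 lower at both numbers. Peg3, expressed from the paternal allele, read 6779 ± 854 in wild-type and 2532 ± 643 in knockout cells (-1.44, SE 0.256) and was the 1 gene that passed when adjusted over the list alone. Meg3 differed by -0.70. Igf2 differed by -2.82 at number 1, where it was bright, and by -0.34 at number 2, where it read 96.9 and 74.6. The median was -0.28 without the filter on dim probe sets (adjusted p = 0.0334), -0.28 without the wild-type array numbered 1 (0.0245) and -0.27 without the knockout array numbered 2 (0.00276).

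Embryonic fibroblast markers fell as a group (camera adjusted p = 0.000688; adjusted p = 0.351 with an estimated correlation), with a median of -0.40 over 13 genes, 12 of them below 0. Within numbers 1 and 2 the medians were -0.14 and -0.32, and 9 of the genes were lower at both. The growth factor receptor gene Pdgfra read 936 ± 819 and 172 ± 54.1 (-2.07; -3.41 at number 1 and -0.74 at number 2). Dcn, which encodes the proteoglycan decorin, read 120.5 ± 24.99 and 39.6 ± 2.49 (-1.38). Abundant markers differed less, with -0.15 for Vim and -0.23 for Col1a2. Of the 13 genes, 4 also stand in another list. The median was -0.24 without the knockout array numbered 2 (adjusted p = 0.00531) and -0.22 without the wild-type array numbered 2 (0.00141).

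Collagens had a median of -0.36 over 16 genes, 14 of them below 0 (camera adjusted p = 0.000688; adjusted p = 0.505 with an estimated correlation). Their medians were -0.10 within number 1 and -0.54 within number 2, and 10 of the genes were lower at both. Col6a2 read 4019 ± 480 and 1682 ± 697 (-1.31), and Col6a1 3979 ± 605 and 2211 ± 40.0 (-0.84). Other matrix and remodelling genes had a median of -0.34 over 21 genes, 19 of them below 0 (camera adjusted p = 0.00312; adjusted p = 0.351 with an estimated correlation). Dcn was at -1.38 (SE 0.334), while fibulin-2 (Fbln2) was higher, at 7839 ± 2591 against 12963 ± 1410 (0.76). No member of either list passed when adjusted over the list alone. The collagen call ended without the knockout array numbered 2 (median 0.16, adjusted p = 0.457) and without the wild-type array numbered 1 (-0.35, 0.125). The call of the other matrix list ended without the same arrays (-0.11 and 0.176, -0.08 and 0.332). Without the wild-type array numbered 2 the medians were -0.70 and -0.59, and without the knockout array numbered 1 that of collagens was -0.92. With the stricter filter the other matrix genes had a median of -0.22.

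All 18 tested genes of cholesterol synthesis were below 0, and 16 of them were lower at both numbers, with a median of -0.34 (95% bootstrap interval -0.51 to -0.23). This list fell under camera (adjusted p = 2.98e-05; adjusted p = 0.549 with an estimated correlation). Fdft1 read 5616 ± 1241 in wild-type and 3502 ± 609 in knockout cells (-0.67) and Mvd 1740 ± 614 and 959 ± 216 (-0.83), and none passed when adjusted over the list alone. Without the wild-type array numbered 2 the call ended (median -0.06, adjusted p = 0.385), and without the knockout array numbered 1 the median was -0.15 (0.0465). Without the wild-type array numbered 1 it was -0.65, and without the knockout array numbered 2 it was -0.54.

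Hox genes, which mark position along the body axis, had a median of -0.32 over 14 genes (camera adjusted p = 0.0118; adjusted p = 0.351 with an estimated correlation). Hoxa5 read 2756 ± 382 and 1160 ± 378 (-1.27; -0.50 by a second probe set), and Hoxa2 388 ± 3.08 and 247 ± 1.27 (-0.63), while 5 of the 14 were above 0. Wnt targets and inhibitors had a median of -0.63 over 10 genes (camera adjusted p = 0.0118; adjusted p = 0.351 with an estimated correlation), with the receptor gene Fzd2 at -0.94 and Ccn5 at -1.19. The Wnt medians were -0.93 within number 1 and -0.19 within number 2. The Hox call ended without the knockout array numbered 2 (median 0.03, adjusted p = 0.287) and without the wild-type array numbered 1 (0.00, 0.332). The Wnt call ended without the knockout array numbered 1 (-0.58, 0.0618) and without the wild-type array numbered 1 (-0.17, 0.535). Without the filter on dim probe sets neither list was called (adjusted p = 0.276 for Hox genes, 0.191 for Wnt genes with a median of -0.26). The Hox median was -0.63 without the knockout array numbered 1 and -0.61 without the wild-type array numbered 2.

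Interferon-stimulated genes had a median of -0.31 over 19 genes (camera adjusted p = 0.0349; adjusted p = 0.595 with an estimated correlation), at -0.77 within number 1 and 0.07 within number 2. Ifitm3 read 10804 ± 2956 and 5455 ± 2363 (-1.03) and Irgm1 1720 ± 125 and 944 ± 31.8 (-0.86). Genes of ATF4 signalling and the unfolded protein response had a median of -0.16 over 24 genes (camera adjusted p = 0.0341; adjusted p = 0.351 with an estimated correlation), with Trib3 at -1.21 and Xbp1 at -0.42. Ribosomal protein genes, taken as a control list, had a median of -0.14 over 21 genes and were called too (camera adjusted p = 0.0128; adjusted p = 0.608 with an estimated correlation), with Rpl6 at -0.24 and Rps18 at -0.23 (other probe sets of Rps18 from -0.51 to 0.05). After quantile normalization all 3 calls ended (adjusted p = 0.0574 for interferon-stimulated genes, 0.0708 for ATF4 signalling and 0.733 for ribosomal proteins with a median of -0.01). They also ended after cyclic loess normalization (0.0734, 0.0738 and 0.503) and without the filter on dim probe sets (0.0642, 0.0642 and 0.0508), and the interferon call ended after median scaling (0.0883). The interferon call also ended without the wild-type array numbered 1 (median 0.29, adjusted p = 0.0718) and without the knockout array numbered 2 (0.17, 0.726). The interferon median was -0.78 without the knockout array numbered 1, -1.13 without the wild-type array numbered 2, -0.56 with the stricter filter and -0.19 with a pseudocount at the median. The ATF4 call was kept only without the wild-type array numbered 2 (without the wild-type array numbered 1 median -0.05 and adjusted p = 0.332, without the knockout arrays numbered 1 and 2 0.38 and 0.0532). The ribosomal call was kept only without the wild-type array numbered 1, with a median of -0.25 (without the wild-type array numbered 2 median -0.05 and adjusted p = 0.576, without the knockout array numbered 1 -0.09 and 0.249, without the knockout array numbered 2 0.056).

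**Figure D4:**
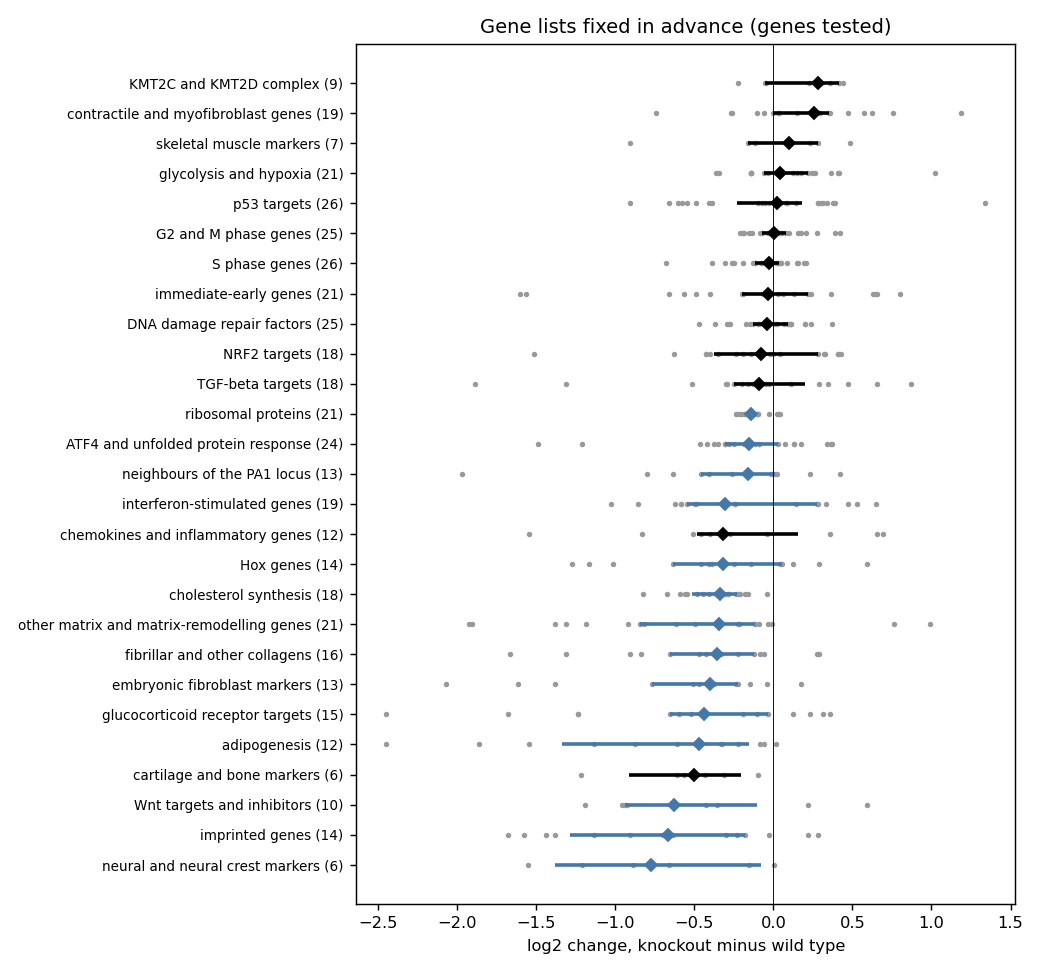
Log2 change, knockout minus wild type, of the tested genes (grey points), with the median (diamond) and its 95% bootstrap interval over genes (bar), for 27 gene lists; the number of genes tested is in parentheses and blue marks the 14 lists that camera called with its preset correlation. Medians run from -0.78 for neural markers to 0.28 for the complex partners, and none of the lists was called with an estimated correlation.

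Cell cycle and damage genes gave medians close to 0 over both numbers together. Within numbers 1 and 2 some medians had opposite signs. They were 0.10 and -0.20 for S phase genes and 0.20 and -0.16 for G2 and M phase genes. For TGF-beta targets they were 0.23 and -0.45, and for chemokine and inflammatory genes 0.16 and -0.65. S phase genes had a median of -0.03 over 26 genes (camera adjusted p = 0.242), with Dscc1 at -0.68 and Mcm7 at -0.26. For G2 and M phase genes it was 0.00 over 25 genes (adjusted p = 0.975), with Cenpe at 0.42 (-0.27 by a second probe set) and Aurka at 0.28. For DNA damage repair factors it was -0.04 (adjusted p = 0.339), with Fanci at -0.47 and H2ax at -0.37. Targets of p53 had a median of 0.03 over 26 genes (adjusted p = 0.513), with Bbc3 at -0.91, Sesn1 at -0.55 and, chosen after its values were seen, Pmaip1 at 1.34. The lists of NRF2 targets (median -0.08, adjusted p = 0.402), glycolysis and hypoxia (0.04, 0.313), TGF-beta targets (-0.09, 0.52) and immediate-early genes (-0.03, 0.145) were not called. Within them, Bmp4 was at -1.88, Tgfbi at -1.31, Egr2 at -1.57, Phlda1 at -0.57, Pfkfb3 at 1.02, Ankrd37 at 0.36, Ugdh at -0.42 and Gstp1 at -0.24. Chemokine and inflammatory genes had a median of -0.32 (adjusted p = 0.248), with Ccl7 at -1.54 and Cxcl12 at -0.40, and without the knockout array numbered 1 they were called (median -1.05, adjusted p = 0.000361), as they were without the filter on dim probe sets (-0.31, 0.0489). Leaving out that array also called S phase (-0.22, 0.0153), G2 and M phase (-0.20, 0.0269) and TGF-beta genes (-0.41, 0.0128). Leaving out the knockout array numbered 2 called p53 targets (-0.37, 0.0374), immediate-early genes (-0.26, 0.0493) and, as higher, G2 and M phase genes (0.20, 0.0451). Signs differed for p53 targets (mean -0.03) and for G2 and M phase genes, whose camera direction was down with a median of 0.00 and a mean of 0.02. Contractile and myofibroblast genes had a median of 0.26 (adjusted p = 0.198), with Smtn at 0.63 and Tpm2 at 0.36, and were called higher after quantile (median 0.35, adjusted p = 0.0228) and cyclic loess normalization (0.32, 0.033).

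Neighbours of Pagr1a on the same chromosome were tested because the floxed allele lies among them. In the RefSeq annotation of assembly GRCm38.p6, Pagr1a lies between Mvp and Prrt2, followed by Maz and Kif22. The list had a median of -0.16 over 13 genes (camera adjusted p = 0.00606; adjusted p = 0.585 with an estimated correlation), with Coro1a at -0.63. Kif22, a chromosome-binding kinesin gene, was the 1 neighbour that passed when adjusted over the list alone. Its brightest probe set read 5634 ± 539 and 1436 ± 185, while its other probe sets read 947 ± 72.9 against 864 ± 71.8 and 1360 ± 57.4 against 1332 ± 11.1. Without Kif22 the list was not called (adjusted p = 0.06). The call also ended without the knockout array numbered 1 (median -0.12, adjusted p = 0.249) and without the wild-type array numbered 2 (0.03, 0.702). The median was -0.34 without the wild-type array numbered 1, -0.29 without the knockout array numbered 2 and -0.08 with the stricter filter.

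Markers of other cell types were mostly dim. Median signals over all measured markers were 30.7 in wild-type and 30.6 in knockout cells for epithelial genes, 30.4 in both for endothelial genes and 20.7 and 20.5 for leukocyte genes. They were 45.8 and 45.7 for cartilage and bone genes, 42.2 and 32.9 for neural genes and 22.3 and 53.3 for skeletal muscle genes. Neural and neural crest markers had a median of -0.78 over 6 genes (camera adjusted p = 0.0162; adjusted p = 0.351 with an estimated correlation). Tubb3 read 707 ± 362 and 253 ± 185 and Ncam1 1820 ± 711 and 949 ± 193, while Nes and Sox10 differed by -0.16 and 0.00. This call ended without the knockout array numbered 2 (median -0.48, adjusted p = 0.168) and without the wild-type array numbered 1 (-0.35, 0.332), and without the filter on dim probe sets (-0.54, 0.11). The median was -1.35 without the knockout array numbered 1 and -1.69 without the wild-type array numbered 2. Cartilage and bone markers had a median of -0.50 over 6 genes (adjusted p = 0.0986), with Col2a1 at -1.22 and Sp7 at -0.44, and were called without the knockout array numbered 1 (-1.07, 0.00338) and without the wild-type array numbered 2 (-0.72, 0.0204). Skeletal muscle markers had a median of 0.10 and a mean of -0.01 over 7 genes (adjusted p = 0.946), with Tnnt2 at 0.48 and Tnni1 at -0.90, and were called higher without the filter on dim probe sets (0.28, 0.0489). The 4 epithelial, 4 endothelial and 3 leukocyte genes were too few to test, with Krt7 at 0.83, Krt19 at 0.46, Flt1 at -0.79, Eng at 0.26, Csf1r at 0.72 and Cd14 at -0.70. The Y-linked genes Kdm5d (381 ± 9.56 and 457 ± 93.7) and Uty (194 ± 54.0 and 215 ± 13.6) were expressed in both groups, with other probe sets of Uty at -0.23 and 0.26, and Xist read 39.3 and 43.3.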

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

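Of the results varied here, the counts at both replicate numbers and the neighbour list without Kif22 were tests chosen after the data had been seen. Under all 3 normalizations, both other pseudocounts, both other filters, both other variance models and the mean of a gene's probe sets, the count of genes past the threshold stayed at 0. Over these settings and with each array left out, the targeted gene ranged from -3.62 to -3.03. That range leaves out the mean of a gene's probe sets, for which its change was not taken. With the replicate number as a block, limma called 447 probe sets (118 higher, 329 lower) and 266 genes (71 higher, 195 lower), 182 of them by at least 2-fold (39 higher, 143 lower), and the targeted gene at -3.51 passed (adjusted p = 1.9e-05). All 16 genes named for size passed under this block, as did 107 of the 109 genes at least 2-fold different at both numbers. Both sets were picked from these same arrays for their genotype differences, so their passing is no independent support. List members were likewise named for a small unadjusted p on these arrays. Of them, Cebpb (limma adjusted p = 0.0018), Peg3 (0.0005), Hoxa5 (0.0032), Col6a2 (0.0031) and Ifitm3 (0.0021) were among those that passed under the block. Trib3 (0.0504), Cxcl12 (0.134) and Hoxa2 (0.14) were among those that did not. Deviations from the group means correlated at 0.805 across probe sets between arrays of the same number, and limma called 3332 genes between the numbers. Arrays of the same number were thus alike beyond their genotype. The labels give no shared origin, so what the arrays of a number share stays unsettled. With 2 pairs the block leaves 1 residual degree of freedom. With the block, camera called 13 lists, 0 with an estimated correlation (smallest adjusted p = 0.734), and fry called 1, other matrix genes (adjusted p = 0.0304). The estimated correlation rests on that 1 degree of freedom, so its count of 0 says little. The block also ended the interferon and ATF4 calls (adjusted p = 0.067 for each) and called cartilage and bone markers (0.0378). Without the block, 0 of the 14 list calls held with an estimated correlation and 0 under fry. With each array left out, 7 to 15 lists were called, 7 without the wild-type array numbered 1, where the lone remaining array is assumed to vary like the others. The count of genes at least 2-fold lower at both numbers was 56 with a pseudocount at the median, 172 without a filter and 41 with the stricter filter, and for genes higher it was 5, 94 and 6. The lower genes made up 81.7% of such genes, 91.8% with the median pseudocount and 64.7% without a filter, where 80 genes went opposite ways. Without the filter 6 list calls ended and 2 other lists were called. The causes were not tested, except that a larger pseudocount shrinks the differences of dim genes and a filter changes how many genes are counted.

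Of the called lists only interferon-stimulated genes turned in camera direction, although the medians of collagens, Hox genes and neighbours also rose above 0 without 1 array. Such fits hold unequal replicate numbers in the 2 genotypes, so their medians also carry part of the difference between numbers. The camera direction of the G2 and M phase list (median 0.003) turned under fry and under the block (0.003 in each), under quantile (0.024) and cyclic loess normalization (-0.002) and without a filter (0.003). With each array left out, medians ran from -0.195 to 0.199 for that list, from -1.13 to 0.287 for interferon-stimulated genes, from -0.366 to 0.233 for p53 targets, from -0.194 to 0.127 for NRF2 targets, from -0.193 to 0.151 for skeletal muscle markers, from -0.221 to 0.096 for S phase genes, from -0.147 to 0.089 for DNA repair factors, from -1.05 to 0.305 for chemokines and from -0.405 to 0.37 for TGF-beta targets. For single genes the ranges were -0.439 to 0.334 for Kmt2c, -0.025 to 0.591 for Rbbp5, -0.166 to 0.067 for Ash2l, -1.56 to 0.158 for Cd14, -0.11 to 0.436 for Uty and -0.943 to 0.072 for Sp7.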

Other observations

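The tests of RNA degradation and of Hox genes below were chosen after the values they measure, or part of them, had been seen, as were the genes named in the next 2 paragraphs.

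Igfbp2, Igfbp4 and Igfbp5, which encode binding proteins of insulin-like growth factors, and Crabp1 and Crabp2 were single genes picked from the 89 at least 2-fold lower at both replicate numbers, and neither gene family was tested as a group. Igfbp2 read 8992 and 57.2 on the wild-type arrays numbered 1 and 2, against 1421 and 10.9 on the knockout arrays. Igfbp4 read 8947 and 2155 against 4151 and 441, and Igfbp5 2502 and 85.9 against 207 and 21.6. Crabp1, a retinoic acid binding protein gene, read 8400 and 2506 against 1107 and 81.5, and Crabp2 748 and 126 against 235 and 32.9. Among the 20 genes higher at both numbers were the signalling genes Syk (343 and 96.2 against 737 and 221) and Plcg2 (296 and 169 against 755 and 459), and Pmaip1 (462 and 39.5 against 1304 and 104). With genotype as the only term, none of these genes passed limma at an adjusted p under 0.05.

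Several position and lineage genes, picked for their size of difference, differed more between the replicate numbers than between the genotypes. Hoxc8 read 1580 and 507 in wild-type and knockout cells at number 1, against 5.31 and 1.56 at number 2. Hoxb9 read 609 and 880 against 17.8 and 33.9, and the T-box gene Tbx1 515 and 541 against 1.13 and 0.91. In the other direction, the zinc finger gene Zic1 read 20.8 and 40.3 at number 1 and 1420 and 1436 at number 2, and the water channel gene Aqp1 781 and 927 against 11290 and 12820. With genotype as a term, limma called 3332 genes between the numbers (adjusted p under 0.05), 1597 higher at number 2 and 1735 higher at number 1. Camera called 6 lists between the numbers, Hox genes not among them (adjusted p = 0.185), and with an estimated correlation the smallest adjusted p was 0.885. That estimate rests on 1 residual degree of freedom, so the absence of calls says little.

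More genes were at least 2-fold lower than higher in the knockout at both numbers, by a ratio of 4.45. The scaling of the arrays does not account for this, since the lowest ratio under 3 other normalizations was 4.29. For damage by Cre acting through p53, the bound set beforehand against it was met. The p53 target list had a median of 0.026, and its upper bound of 0.183 lay below that bound. Within numbers 1 and 2 the medians were 0.013 and 0.059. A rule outside that prediction kept it undecided, as it takes a median near 0 with genes on both sides to decide nothing. By that rule a list without any shift would also stay undecided. Here 14 genes lay above 0 and 12 below, and the median moved with the array left out. It was 0.225 without the knockout array numbered 1 and 0.233 without the wild-type array numbered 2. Without the wild-type array numbered 1 it was -0.309, and without the knockout array numbered 2 it was -0.366. Those medians also carry part of the difference between numbers, whose median for this list was 0.59. A loss of cells of another type met its prediction but stays open. The median over 30 markers of other cell types was -0.159 with a lower bound of -0.501, narrowly short of the -0.5 set beforehand against it. The types did not move together. Tested markers had medians of 0.39 for epithelial, 0.10 for skeletal muscle and 0.02 for endothelial genes. For leukocyte and for cartilage and bone genes the medians were -0.32 and -0.50. Of 17 neural markers measured, 11 were too dim to be tested. The neural list was called at a median of -0.78, although Nes and Sox10 differed by -0.16 and 0.00. That call was lost in camera with an estimated correlation (adjusted p = 0.351). This setting recovered 0 of 10 simulated list shifts with moderated spreads and 9 with unmoderated ones, with noise independent between genes. A dependence of these genes on PA1 may also explain the pattern and was not tested apart from it.

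Kif22 was lower by 1 probe set of 3. The other probe sets differed by -0.13 and -0.03, so a candidate explanation is a probe set that does not measure Kif22. Fewer cells in mitosis is argued against by the 25 G2 and M phase genes, whose median had a lower bound of -0.0715 against the -0.984 that this explanation needed. A lower output of all neighbours is argued against in the same way by the other 12 neighbours, with a lower bound of -0.432. The sequences of the probes were not used here, so what the probe set measures stays open.

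Arrays resembled the array of the same replicate number more than the other array of their genotype. An intensity-dependent difference between arrays is argued against by the correlation of deviations, 0.805 before and at least 0.804 after quantile and cyclic loess normalization. RNA degradation is argued against by the actin and GAPDH controls, whose 3' to 5' log2 ratios differed by at most 0.123 between numbers. A different growth state cannot be told apart, since the lower adjusted p of the S phase and G2 and M phase lists was 0.0639 with medians of -0.216 and -0.212. Different cell populations behind the numbers, such as separately derived lines, may be a source but stay unsettled. The Hox genes had a median absolute difference of 0.642 against 0.391 in 10000 matched random lists. This was percentile 93.5, short of the 95 set for the test. The random lists came from the same differences between numbers, in which limma called 3332 genes. Different populations could raise both values, so the percentile speaks neither for nor against them.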
